A study of Mus musculus with 2 samples.

How the data were processed

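Single-cell RNA sequencing was run on colon from mice with colitis induced by dextran sulfate sodium (DSS), a polysaccharide that injures the colon lining when given in drinking water. The labels give 1 group of 2 libraries, numbered as repeats 1 and 2, and no untreated sample was used here, so nothing below describes an effect of DSS. The mice were 7 weeks old, were kept free of specific pathogens and had 3% DSS over 6 days before the middle part of the colon was taken. The labels do not say that the repeats came from separate animals. The p-values below therefore measure only the spread between these samples, which may be technical.

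The deposited matrices hold UMI counts per gene and cell barcode, and the authors made them with Cell Ranger: the file headers name version 7.0.0 and the submitters' processing notes name version 8.0.0. The notes name the mouse build mm10, and the annotation is not given in the sources used here. Per the labels' protocols, cells were captured with a 3' V3 kit and libraries were made with 3' v2 reagents, a conflict that the labels leave open. The matrices list 55357 genes, of which 52081 gene IDs were found in the GENCODE M21 annotation of GRCm38 (mm10). Coordinates come from that annotation. The protocol aimed at 5000 cells per library, and the files hold 6597 and 9611 barcodes.

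Library 1 held 76622643 UMIs and library 2 held 94204110, with medians of 7234 and 6400 UMIs per barcode. Barcodes were kept with at least 200 genes detected and under 20% mitochondrial UMIs. The first filter removed 36 barcodes of library 1 and 9 of library 2, and 876 (13.3%) and 484 (5.04%) barcodes lay above the mitochondrial limit. Scrublet scores were computed per library in scanpy 1.11.5, and the highest scorers were removed at an expected rate of 0.8% per 1000 barcodes, which took out 302 and 702 barcodes. This left 5419 and 8425 cells with medians of 7923 and 6454 UMIs. A chi-square test of the summed counts over 22690 genes gave 3760725 on 22689 degrees of freedom, 165.8 per degree of freedom. Because the mix of cells also differed, this excess over counting noise does not show that the libraries came from separate tissue. They were counted as separate samples because the labels number them as repeats.

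Cells of both libraries were clustered together on log-normalised counts (10000 per cell) with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. The genes of the 15 fixed lists, and mitochondrial, ribosomal, haemoglobin, immunoglobulin, Xist and Y-linked genes, were held out of the clustering. List genes thus did not themselves define the classes, but genes that vary with them stayed in, so the classes are not independent of the lists. Each cluster was named from marker genes fixed beforehand for 16 classes. All class names mean "like" cells of that type by these markers (neutrophil-like, fibroblast-like and so on). Where a class has subtype lists, its markers and those of its subtypes were scored together. A cluster stayed unnamed with fewer than 3 detected markers (10 CPM), with more markers of another class than of its own among its 10 leading genes, or with a median UMI count below its libraries' median divided by 3 and no own marker among those genes. It also stayed unnamed when fewer than 50% of its cells held 2 of the markers. This scoring and the last condition were set after the clusters had been seen. They left 5.24% of library 1 and 4.07% of library 2 unnamed. Epithelial cells were clustered again alone and named in the same way, with leading genes also compared with markers of the other classes. That left 16.4% and 5.71% of epithelial cells unnamed.

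Raw counts were summed per library and class. Classes with at least 20 cells in each library entered an edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with TMM normalisation, filterByExpr and the library as a block, since all classes of a library come from the same colon sample. The fit held 18 sums of 9 classes and 14349 genes with 8 residual degrees of freedom. A second fit of 6 sums held 3 epithelial subclasses, 13975 genes and 2 residual degrees of freedom. A gene's source class is the class with the highest mean, called when the largest of its p-values against the other classes was under 0.05 after Benjamini-Hochberg adjustment over the list genes. Each class was also tested against the mean of the others, and 3 pairs of classes were compared, with adjustment over all genes tested and, separately, over the list alone. Log2 fold changes are given as value ± SE, where the SE is the one implied by the fold change and its p-value. Levels are CPM, counts scaled to a common total, as mean ± SD over the 2 libraries. CPM beside a test are TMM-normalised, which about doubles neutrophil values (normalisation factors 0.485 and 0.509). It also raises plasma cell values (0.640 and 0.705) and lowers lymphoid values (1.21 and 1.23). CPM in accounts of free RNA, of the libraries' difference and of tests of explanations are plain. Shares carry exact Clopper-Pearson 95% intervals. These intervals, and folds against classes with at most 3 counts, cover counting error only. A fold against a class with 0 counts is a lower bound, computed against 3 counts over both libraries.

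Before the data were examined, 15 lists with 364 genes were fixed, of which 361 genes were found. Ctgf, Cyr61 and Ero1l were not found under these symbols, and their newer symbols are in the lists. Genes named in the text follow a rule fixed at the same time. It takes up to 4 called list genes per class by lead over the second class, with at least 10 CPM and the same top class in both libraries. It takes up to 12 list genes each way per pair of classes by fold change, with the same direction in both libraries, and 33 genes always given whatever they show. Between the libraries it takes the 10 genes with the largest ratio among those with 50 CPM in either library. A gene that this rule names is not reported here. Members named only as examples of a list's count were chosen after their values were seen. A list's median ratio between the libraries was set against 10000 random lists of the same size, matched on expression.

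Counts were simulated with all classes at a shared profile and no library effect. The fit was tested on these counts with 50 genes changed at each fold size. Of genes changed 2-fold, it recovered 86% for neutrophils against phagocytes (12264 genes), 42% for fibroblasts against endothelium (12296 genes) and 98% for colonocytes against undifferentiated epithelium (13354 genes). At 4-fold these shares were 100%, 96% and 100%. It called 0.124%, 0.0413% and 0.0988% of unchanged genes. In the data many more genes differ between classes, 3384 and 4114 of 14349 for neutrophils against phagocytes. The simulated rates therefore do not cover errors from composition or normalisation. Alternatives were DESeq2 1.42.0, DESeq2's size factors, no filter on low counts, no block, a minimum of 50 cells, other limits on genes and mitochondrial UMIs, other treatment of doublets, Leiden resolutions 0.5 and 2.0, libraries clustered apart, list genes kept in the clustering, and each library left out. With 2 libraries of 1 group, no regrouping of samples was possible. Other tools were anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and limma 3.58.1.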

Results

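Single-cell counts were measured in 2 libraries of 1 group, mid-colon of mice with DSS colitis, with 76622643 UMIs in library 1 and 94204110 in library 2. The question was which cells were present and which of them carried the transcripts of inflammation, matrix breakdown and epithelial repair. After filtering, 5419 cells of library 1 and 8425 cells of library 2 fell into 10 named classes. T, NK and innate lymphoid cells made up 30.7% ± 0.469 of cells (SD, n = 2), at 31.0% of library 1 (95% interval 29.8 to 32.3) and 30.3% of library 2 (29.4 to 31.3). Epithelial cells were 33.2% of library 1 (31.9 to 34.5) and 14.1% of library 2 (13.4 to 14.9), a mean of 23.7% ± 13.5. Mononuclear phagocytes went the other way, with 15.1% (14.2 to 16.1) and 31.5% (30.5 to 32.5), a mean of 23.3% ± 11.5. Neutrophils made up 9.54% ± 2.11, B cells 3.04% ± 0.538, fibroblasts 1.70% ± 0.389, endothelial cells 1.42% ± 0.280, plasma cells 1.23% ± 0.0312 and mast cells 0.539% ± 0.0734. Smooth muscle cells and pericytes (0.256% ± 0.0234, 36 cells) were too few to test. The immune classes together held 58.7% of library 1 and 77.9% of library 2. With 1 condition and 2 libraries these shares carry no test. The epithelial difference lay mostly in a colonocyte cluster with 746 cells in library 1 and 172 in library 2, and the phagocyte difference in a cluster closest to macrophages (120 and 798 cells) and one closest to monocytes (141 and 748 cells).

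**Figure D1:**
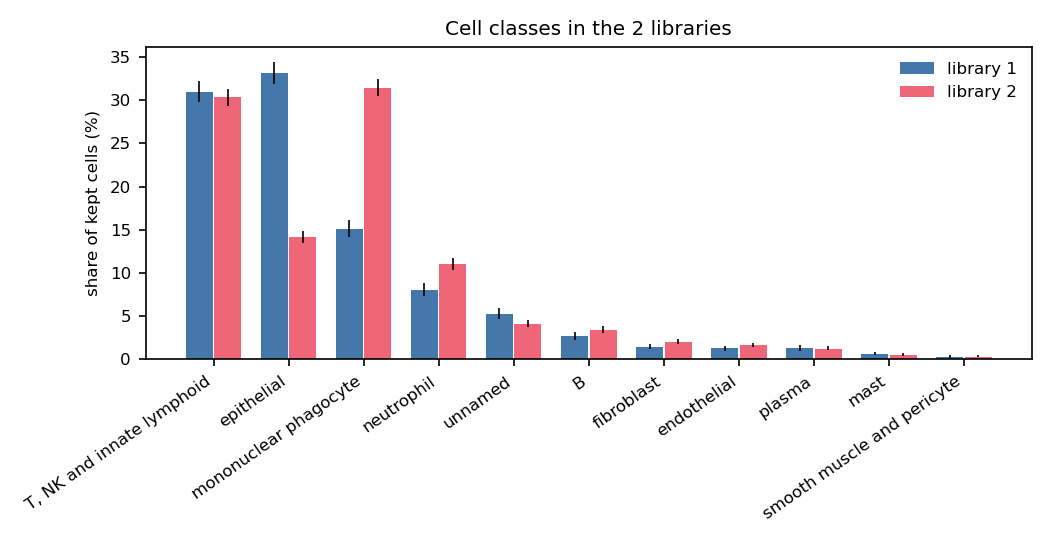
Share of kept cells (percent, y axis) in each cell class (x axis) for library 1 (blue bars) and library 2 (red bars), with exact 95% binomial intervals as error bars. Lymphoid cells held 31.0% and 30.3%, while epithelial cells held 33.2% and 14.1%.

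Within the epithelium, colonocytes, the absorptive cells of the surface, were 60.1% of epithelial cells in library 1 (57.8 to 62.4) and 62.4% in library 2 (59.6 to 65.1). Undifferentiated cells, which hold the stem and dividing cells, were 13.4% (11.9 to 15.1) and 19.98% (17.7 to 22.4), and mucus-making goblet cells were 7.89% (6.69 to 9.24) and 10.7% (8.97 to 12.6). Enteroendocrine cells were 1.67% and 1.09%, and tuft cells 0.5003% and 0.168% (9 and 2 cells). Unnamed subclusters held the rest, 16.4% and 5.71%. Among these, 1 was led by Ly6g and held 196 and 29 cells, another held 25 and 18 cells led by neutrophil genes, another 18 and 21 cells led by T cell genes such as Gzma and Cd3e, and another 56 and 0 cells of low UMI count led by Mmp3 and Dcn. All stayed in the sums of the epithelial class. A colonocyte subcluster of 322 and 9 cells and one of 123 and 6 cells also came mostly from library 1. Among the classes tested, medians of UMIs per cell ranged from 2347 in B cells of library 2 to 23097 in epithelial cells of library 2.

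The first comparison asked which class carried each list gene. Of 336 list genes tested, 219 had a source class (219 when adjusted over the list alone), with 52 in fibroblasts, 51 in epithelium, 40 in neutrophils, 34 in phagocytes, 17 in endothelium, 9 in lymphoid cells, 7 in plasma cells, 5 in mast cells and 4 in B cells. These counts moved with the processing: with a minimum of 500 genes per cell, fibroblasts had 22 and the smooth muscle and pericyte class 30, with no doublets removed fibroblasts had 33 and phagocytes 20, and with DESeq2 phagocytes had 17, endothelium 11 and mast cells 3. Stem cell niche factors, secreted signals that keep crypt stem cells, had a source in 18 of 18, and 14 of these were fibroblast genes. Matrix proteases and inhibitors had one in 21 of 25 (23 adjusted over the list alone), 12 of them in fibroblasts, and growth factors in 12 of 20, 8 of them in fibroblasts. Antimicrobial and mucosal defence genes had one in 19 of 20, with 13 in epithelium, 4 in neutrophils and 2 in phagocytes. Inflammasome and cell death genes had one in 17 of 24, 11 of them epithelial, and hypoxia and glycolysis genes in 12 of 23, 7 of them epithelial. Cytokines had one in 19 of 30, with 6 in phagocytes, and chemokines in 22 of 31 (23 adjusted over the list alone), with 8 in phagocytes and 7 in fibroblasts. Receptors for these had one in 18 of 26, with 9 in neutrophils. Eicosanoid enzymes and receptors had one in 12 of 21, MHC class II presentation genes in 9 of 12, fetal-like epithelial repair genes in 12 of 20 and dissociation stress genes in 12 of 22. Interferon-stimulated genes and proliferation genes had fewer calls, with a source in 10 of 23 and 7 of 22 (8 and 6 adjusted over the list alone), 6 of the latter 7 in plasma cells.

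Neutrophils were the source of granule genes and of several mediators. Ngp, a granule protein (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), stood at 22736 ± 593 CPM (SD, n = 2) and led the second class by 9.16 ± 1.17 on the log2 scale (edgeR adjusted p = 6.96e-13). Ltf (2633 ± 393 CPM), Camp (2261 ± 145 CPM) and the gelatinase Mmp9 (2801 ± 123 CPM) followed with leads of 8.65 ± 1.03, 8.43 ± 1.11 and 6.53 ± 0.86. Lcn2, an iron-sequestering protein, reached 23215 ± 2216 CPM with a lead of 2.63 ± 0.57 over endothelium (adjusted p = 1.28e-05). Anxa1, from the epithelial repair list, was also a neutrophil gene here, at 5347 ± 280 CPM against 264 ± 58.0 CPM in epithelium (lead 4.37 ± 0.62). The neutrophil chemoattractant Cxcl2 stood at 20160.4 ± 2006 CPM in neutrophils and 7860 ± 2609 CPM in phagocytes (lead 1.31 ± 0.48, adjusted p = 0.0105). Osm, an IL-6 family cytokine, stood at 636 ± 6.46 CPM and 275 ± 56.2 CPM (lead 1.201 ± 0.29, adjusted p = 7.85e-05). The call for Cxcl2 ended when no doublets were removed, at a lead of 1.197. In plain CPM Cxcl2 stood at 10006 ± 659 in neutrophils and 7252 ± 2209 in phagocytes, so the size of this lead depends on the normalisation.

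Phagocytes carried the highest Saa3, an acute-phase protein, at 16825 ± 1853 CPM, with 9929 ± 5524 CPM in fibroblasts (lead 1.02 ± 0.37, adjusted p = 0.011). Nos2, which makes nitric oxide, stood at 521 ± 197 CPM in phagocytes and 282 ± 47.6 CPM in neutrophils (lead 0.85 ± 0.28, adjusted p = 0.0055). The chemokines Ccl9 (424 ± 45.6 CPM), Cxcl16 (477 ± 61.6 CPM) and Pf4 (103 ± 78.7 CPM) led by 3.65 ± 0.56, 2.77 ± 0.44 and 3.11 ± 0.59, and Il12b, at 17.9 ± 7.51 CPM, was 32.9 times as high as in neutrophils (counting interval 9.06 to 273). Il1b had no source class, with 7501 ± 801 CPM in phagocytes and 7469.7 ± 809 CPM in neutrophils (adjusted p = 0.991), nor did Tnf, with 245 ± 54.8 and 242 ± 80.4 CPM (adjusted p = 0.933). These ties are on the TMM scale. In plain CPM Il1b stood at 6944 ± 543 in phagocytes and 3707 ± 277 in neutrophils. Il10 stood at 60.9 ± 46.8 CPM in phagocytes and 46.5 ± 16.5 CPM in lymphoid cells (adjusted p = 0.544), and the prostaglandin enzyme Ptgs2 at 1642 ± 99.0 CPM in phagocytes and 857 ± 94.4 CPM in fibroblasts (adjusted p = 0.057). The calls of Saa3 and Nos2 ended with DESeq2, at leads of 0.85 and 0.66, and when no doublets were removed, at leads of 1.35 and 0.69.

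Fibroblasts carried matrix enzymes, niche signals and several cytokines. The stromelysins Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975) and Mmp10 stood at 1716 ± 219 and 1035 ± 166 CPM, leading neutrophils by 7.78 ± 1.002 and 7.41 ± 0.86 (adjusted p = 1.41e-11 and 2.39e-13). The Wnt inhibitor Sfrp1 (918 ± 299.8 CPM), the growth factor Igf1 (973 ± 276 CPM), the eosinophil chemoattractant Ccl11 (427 ± 30.2 CPM) and the alarmin Il33 (532 ± 84.4 CPM, lead 4.56 ± 0.62 over endothelium) were fibroblast genes too. Il11, an IL-6 family cytokine on chromosome 7, stood at 923 CPM in library 1 and 238 CPM in library 2, 256 times the mast cell level (counting interval 45.9 to 10128). The chemokines Cxcl5 and Cxcl13 stood at 628 ± 105 and 489.7 ± 126 CPM, with leads of 5.06 ± 0.61 and 4.77 ± 0.75. The BMP antagonist Grem1 was at 631 ± 110 CPM and Wnt5a at 262 ± 141 CPM, 119 (40.5 to 575) and 129.9 (23.3 to 5139) times the mast cell level. Timp1, a protease inhibitor, stood at 350.2 and 1020.0 CPM in the libraries (lead 2.65 ± 0.57), and Rspo3, a Wnt amplifier, at 40.3 ± 15.6 CPM (lead 1.84 ± 0.57, adjusted p = 0.0028). Wnt2b, with 5 fibroblast counts, was below the filter. With a minimum of 500 genes per cell, fibroblasts made up 0.898% and the smooth muscle and pericyte class 1.47% of cells, and the latter then led for Il11, Mmp3, Mmp10, Cxcl5, Cxcl13, Wnt5a and Grem1 (the fibroblast value relative to it was -10.35 for Mmp10 and -0.045 for Grem1). That class also led for Mmp3 and Mmp10 with no doublets removed (-0.34 and -0.39) and at Scrublet's automatic threshold (-0.45 and -0.50). Epithelium led for Il11 and Mmp10 at Leiden resolution 0.5 (-0.95 and -5.21). The fibroblast class then held 39 and 97 cells, the same numbers as the main fibroblast cluster led by Lum, and epithelium 2002 and 1400. With 500 genes, fibroblasts held 36 and 91 cells and the smooth muscle and pericyte class 74 and 125. By these numbers the fibroblast cluster led by Ereg and Il11 had other class names at these settings. The turns there do not show another source. This does not cover the turns under the doublet settings. With no doublets removed, fibroblasts held 128 and 293 cells and the smooth muscle and pericyte class 24 and 38. The main fit left the latter class out, so its fibroblast calls were not tested against that class.

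Endothelial cells were the source of the lymphatic chemokine Ccl21a (2094 ± 625 CPM, lead 9.20 ± 1.08), the vessel factors Angpt2 (389 ± 130.4 CPM, lead 7.48 ± 0.99) and Pdgfb (278 ± 74.9 CPM, lead 3.96 ± 0.57), the Notch ligand Dll4 (53.3 ± 2.01 CPM, lead 4.19 ± 0.72) and Clu (151 ± 14.1 CPM, lead 1.02 ± 0.34, adjusted p = 0.0045). The monocyte chemoattractant Ccl2 was called endothelial at a lead of 0.81 ± 0.34 (adjusted p = 0.028), with 143 CPM in library 1 and 606 CPM in library 2 against 154 and 232 CPM in fibroblasts. Library 1 alone put fibroblasts first, with an endothelial lead of -0.10, and library 2 alone gave 1.38. The smooth muscle and pericyte class led for Ccl2 with no doublets removed (endothelial lead -0.27) and at Scrublet's automatic threshold (-0.26). Cxcl1 stood at 598 ± 297 CPM in endothelium and 588 ± 22.7 CPM in fibroblasts (adjusted p = 0.926).

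Epithelial cells carried the lectins Reg3b and Reg3g, which act on bacteria, at 4417 ± 2080 and 893 ± 506 CPM, with leads of 3.70 ± 0.51 and 3.58 ± 0.51 (adjusted p = 1.07e-11 and 6.20e-11). Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) stood at 5887 CPM in library 1 and 2946 CPM in library 2. Dmbt1 (2339 ± 884 CPM), the inflammasome gene Nlrp6 (203 ± 26.8 CPM) and the cornified envelope gene Sprr1a (53.2 ± 3.05 CPM) led by 3.69 ± 0.48, 4.12 ± 0.58 and 3.64 ± 0.53. The EGF receptor ligand Areg stood at 202 ± 48.2 CPM (lead 2.497 ± 0.51), and Ccl20 at 14.2 ± 9.28 CPM, 7.52 times the B cell level (counting interval 2.57 to 36.5). Ly6a was high in several classes and had no source, with 2120 ± 54.4 CPM in epithelium and 1501 ± 328 CPM in plasma cells (adjusted p = 0.162). The calls of Reg3b and Reg3g ended when the libraries were clustered apart, at leads of 1.03 and 1.12.

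Lymphoid cells were the source of the type 1 cytokine Ifng (236 ± 4.04 CPM, lead 5.21 ± 0.73) and the receptor Cxcr6 (188 ± 2.25 CPM, lead 4.22 ± 0.77). Their type 17 cytokines differed between the libraries, with Il22 at 139 and 21.2 CPM and Il17a at 55.9 and 6.12 CPM. They stood 67.5 (18.7 to 558) times the endothelial level and 42.4 (7.58 to 1675) times the B cell level. Mast cells carried the type 2 cytokines Il4 (60.9 ± 33.7 CPM, 92.4 times the B cell level, interval 15.5 to 3751) and Il13 (29.9 ± 5.81 CPM, lead 5.62 ± 1.30), the prostaglandin D2 synthase Hpgds (239 ± 41.5 CPM, lead 2.90 ± 0.48) and the highest Jun (1493 ± 643 CPM, lead 0.75 ± 0.29). Il6 was highest in mast cells at 222 and 44.2 CPM, without a call (adjusted p = 0.128). The mast cell class was a single cluster of 32 and 41 cells. Its leading genes included Mcpt8, a marker of the eosinophil and basophil class, which came second for this cluster (score 2.37 against 8.47). Basophil-like cells within it were not told apart from mast cells. B cells carried the antigen presentation genes H2-Ob (307 ± 25.3 CPM, lead 4.98 ± 0.67), H2-Oa (165 ± 22.7 CPM, lead 2.66 ± 0.43) and Ciita (225 ± 35.6 CPM, lead 1.03 ± 0.30), and the receptor Cxcr4 (253 ± 13.8 CPM, lead 1.46 ± 0.31). Plasma cells carried the cell cycle genes Mki67 (632 ± 99.8 CPM), Rrm2 (144 ± 34.3 CPM), Ccna2 (91.5 ± 17.4 CPM) and Ccnb1 (46.8 ± 2.70 CPM), with leads over lymphoid cells of 1.07 ± 0.26, 1.87 ± 0.40, 0.98 ± 0.30 and 1.03 ± 0.32. The size of these leads depends on the normalisation, which raises plasma cell values and lowers lymphoid ones. Its factors were 0.640 and 0.705 in plasma cells and 1.21 and 1.23 in lymphoid cells. The calls of Il4 and Il13, and that of Il12b in phagocytes, ended with DESeq2.

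**Figure D2:**
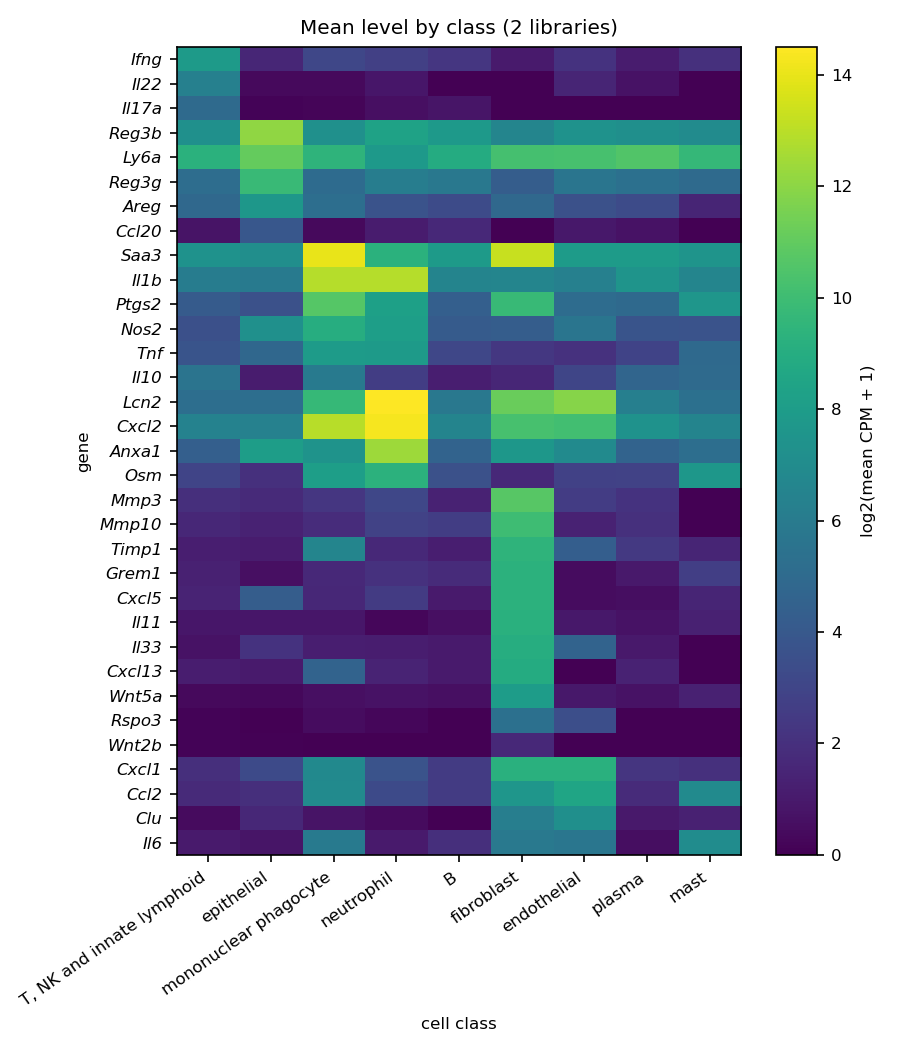
Mean level over the 2 libraries, as log2(TMM-normalised CPM + 1) by colour, of the 33 genes given whatever they show (y axis), in each of the 9 tested classes (x axis). Il1b stood at 7501 CPM in phagocytes and 7469.7 CPM in neutrophils, and Mmp3 at 1716 CPM in fibroblasts.

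Against the mean of the other classes, phagocytes had the most list genes higher, 179 of 336 (183 adjusted over the list alone), with 53 lower (56). In epithelium 146 were higher and 84 lower (147 and 84), in fibroblasts 135 and 105 (136 and 108), in neutrophils 135 and 50 (135 and 49), and in endothelium 100 and 70 (102 and 78). Lymphoid cells had 64 higher and 118 lower (64 and 119), mast cells 50 and 61 (56 and 66), plasma cells 40 and 114 (41 and 117) and B cells 27 and 104 (29 and 113). With DESeq2, 185 were lower in lymphoid cells and 80 in phagocytes, and in epithelium 129 were higher and 135 lower. With no doublets removed, 41 were lower in endothelium and 34 in mast cells. All 12 MHC class II presentation genes were higher in phagocytes and 11 in B cells. All 22 proliferation genes were higher in lymphoid cells and in plasma cells, and 17 in epithelium. Of 23 interferon-stimulated genes, 20 were higher in phagocytes, 18 in epithelium and 18 in neutrophils. Of 23 hypoxia and glycolysis genes, 20 were higher in epithelium, and of 25 matrix genes, 22 in fibroblasts. Dissociation stress genes, which tissue digestion can induce, were higher in phagocytes for 15 of 22, in neutrophils for 13 and in mast cells for 10.

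Neutrophils and phagocytes, the myeloid classes of the inflamed colon, were compared over the 15 lists. Antimicrobial genes leaned to neutrophils (14 of 20 higher, 2 lower), as did receptors (12 of 26 higher, 7 lower), while chemokines (3 of 31 higher, 18 lower) and MHC class II presentation genes (1 of 12 higher, 11 lower) leaned to phagocytes. Higher in neutrophils were Camp, Ngp, Ltf and Mmp9, by 9.54 ± 1.16, 9.16 ± 1.17, 8.76 ± 1.05 and 8.66 ± 1.06 on the log2 scale. The glucose transporter Slc2a3 stood at 456 ± 36.5 against 3.62 ± 0.837 CPM, the leukotriene enzyme Alox5 at 205 ± 20.8 against 1.76 ± 0.952 CPM, and the myeloid growth factor Csf1 at 85.2 ± 13.0 against 3.23 ± 0.142 CPM. Anxa1, Lcn2, Mmp25, Il1rap and Il18r1 followed with differences of 4.92 ± 0.68, 4.78 ± 0.78, 4.42 ± 0.53, 3.99 ± 0.51 and 3.58 ± 0.56. Higher in phagocytes were the antigen presentation genes Cd74 (8759 ± 57.0 against 273 ± 87.4 CPM in neutrophils), H2-Aa (4054 ± 51.2 against 128 ± 39.4 CPM), H2-Eb1 and Cd40, the proteases Mmp14 (415 ± 32.8 against 5.88 ± 0.0832 CPM) and Mmp12, and Timp1, Nrg1, Cxcl16, Saa3 and Il12b. The cytokine Il6 stood at 61.4 ± 20.1 CPM in phagocytes and at 6 counts in neutrophils, a difference of -5.37 ± 1.10 (adjusted p = 6.69e-06).

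Of all 336 list genes tested, 89 were higher in neutrophils and 110 higher in phagocytes (89 and 110 adjusted over the list alone), and over all 14349 genes these counts were 3384 and 4114. Il1b (-0.01 ± 0.42, adjusted p = 0.999) and Tnf (-0.02 ± 0.22, adjusted p = 0.947) did not pass on the TMM scale, though Il1b in plain CPM was higher in phagocytes. Osm (1.201 ± 0.29) and Cxcl2 (1.31 ± 0.48, adjusted p = 0.0142) were higher in neutrophils, and Ptgs2 (-2.44 ± 0.57), Il10 (-3.41 ± 0.64), Cxcl1 (-3.32 ± 0.55), Ccl2 (-3.91 ± 0.66), Cxcl13 (-3.38 ± 0.96), Areg (-1.51 ± 0.55), Ly6a (-1.59 ± 0.39) and Nos2 (-0.85 ± 0.28) were higher in phagocytes. Other lists were split, with cytokines 6 higher and 11 lower, hypoxia and glycolysis genes 10 and 8, inflammasome genes 7 and 9, matrix genes 9 and 7, eicosanoid genes 7 and 8, interferon-stimulated genes 4 and 7, dissociation stress genes 6 and 8, epithelial repair genes 7 and 4, growth factors 1 and 6, niche factors 2 and 1 and proliferation genes 1 and 3. Genes of the epithelium were among the 14 antimicrobial genes higher in neutrophils, at levels much like those in other classes. Reg3b, for example, was at 163 ± 10.7 plain CPM in neutrophils and 143 ± 13.8 in phagocytes, while other classes outside the epithelium had 101 to 295. The passes of Reg3b, Reg3g, Cxcl2 and Nos2 ended when no doublets were removed.

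Fibroblasts and endothelial cells, the main stromal classes, differed in several lists of secreted factors. Niche factors were higher in fibroblasts for 14 of 18 and higher in endothelium for 3, and matrix proteases and inhibitors for 17 and 4 of 25, eicosanoid genes for 11 and 2 of 21, growth factors for 10 and 5 of 20 and chemokines for 9 and 2 of 31. Endothelium had 0 counts of the chemokines Cxcl13 and Cxcl14, the growth factors Fgf7 and Fgf10, the BMP ligands Bmp5 and Bmp7, the Wnt modulators Dkk3, Sfrp2 and Rspo1, and the prostacyclin receptor Ptgir. Fibroblast levels of these were at least 287, 103, 174, 12.4, 96.9, 61.9, 46.4, 19.4, 12.7 and 16.6-fold higher, in that order. The collagenase Mmp13 was 1322 times (452 to 6410) and the EGF receptor ligand Ereg 1672 times (300.0 to 66080) the endothelial level. Endothelial cells had at least 361-fold higher Pdgfb, 514 times (175 to 2499) the fibroblast level of Angpt2, 97.3 times (26.3 to 814) that of Dll4, 25.5 times (6.41 to 221) that of Ltc4s and 13.9 times (4.16 to 72.3) that of Ciita. Ccl21a (-10.84 ± 1.28), Hbegf (-5.39 ± 0.94), Rsad2 (-4.42 ± 0.82), Cxcr4 (-4.10 ± 0.70), Jag1 (-3.95 ± 0.76) and Pdgfa (-3.67 ± 0.53) were higher in endothelium too. Endothelial Rsad2 differed between the libraries, at 33.8 plain CPM in library 1 and 366 in library 2.

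Of the 336 list genes, 86 were higher in fibroblasts and 73 in endothelium (89 and 81 adjusted over the list alone), and over all 14349 genes 1967 and 1685. Hypoxia and glycolysis genes were higher in endothelium for 14 of 23 and in fibroblasts for 2, with Hk1 and Pgk1 among the 14. Interferon-stimulated genes were higher in endothelium for 8 of 23, Irf7 and Gbp2 among them. MHC class II presentation genes were split 1 and 5, inflammasome genes 2 and 7, cytokines 8 and 5, receptors 5 and 4, epithelial repair genes 4 and 6, antimicrobial genes 2 and 5 and dissociation stress genes 1 and 3, and 1 proliferation gene was higher in endothelium. Mmp3 (8.66 ± 1.14), Timp1 (5.10 ± 0.88), Saa3 (5.28 ± 0.78), Il33 (4.56 ± 0.62), Ptgs2 (4.49 ± 0.82) and Rspo3 (1.84 ± 0.57) were higher in fibroblasts, and Clu (-1.02 ± 0.34), Nos2 (-1.34 ± 0.44), Reg3b (-0.73 ± 0.28) and Reg3g (-1.09 ± 0.40) in endothelium. Ccl2 (-0.81 ± 0.34, adjusted p = 0.0641), Lcn2 (-0.88 ± 0.45), Anxa1 (0.73 ± 0.34), Cxcl1 (-0.03 ± 0.25) and Ly6a (-0.02 ± 0.31) did not pass. When no doublets were removed, Reg3b and Reg3g turned to 1.05 and 0.93 in favour of fibroblasts. Reg3b, an epithelial gene here, stood at 219 ± 96.4 plain CPM in endothelium and 114 ± 28.1 in fibroblasts. The epithelial genes Krt8 (342 and 139), Epcam (222 and 58.8) and Lgals4 (251 and 125) also had higher means in endothelium. For Reg3b and Reg3g, expression by endothelium was thus not told apart from epithelial RNA counted there.

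Colonocytes and undifferentiated epithelium differed in defence and in division. Part of this may be built in, since genes that vary with the lists stayed in the clustering. Prc1 and Nusap1 were among the leading genes of an undifferentiated subcluster, and Slfn2 and Irgm2 among those of a colonocyte subcluster. All 24 interferon-stimulated genes tested were higher in colonocytes, among them Ifit2 (575 ± 139 against 9.26 ± 5.60 CPM), Ifit1 (5.88 ± 1.06 on the log2 scale), Rsad2 (5.61 ± 0.996), Irf7 (4.89 ± 0.83), Isg15 (649.7 ± 7.83 against 23.3 ± 4.96 CPM) and Oasl1 (4.58 ± 0.76). The acute-phase genes Saa1 (5571 ± 2901 against 72.8 ± 55.8 CPM) and Saa2 (6.42 ± 1.05), Nos2 (389 ± 98.7 against 15.4 ± 1.15 CPM), the oncostatin receptor Osmr (4.80 ± 0.97) and the cornified envelope genes Sprr1a (4.79 ± 1.02) and Sprr2h (4.64 ± 0.89) were higher as well. All 22 proliferation genes were higher in undifferentiated cells, among them Mki67 (356 ± 92.7 against 26.0 ± 23.3 CPM in colonocytes), Top2a (353 ± 153 against 19.2 ± 13.3 CPM), Aurkb (-4.75 ± 0.81), Cenpf (-4.47 ± 0.94), Mcm2 (-4.45 ± 0.77), Mcm6 (-4.30 ± 0.76), Ccnb1 (-4.12 ± 0.82), Ccna2 (-4.09 ± 0.78), Plk1 (-4.08 ± 0.79), Stmn1 (-3.98 ± 0.78) and Cdk1 (-3.96 ± 0.77). The oxidase Nox1 was the antimicrobial gene higher in undifferentiated cells, at 42.8 ± 5.52 against 1.98 ± 0.225 CPM. Ly6a (4402 ± 446 against 607 ± 70.3 CPM), Areg (2.89 ± 0.64), Anxa1 (1.83 ± 0.36), Reg3b (1.88 ± 0.47) and Reg3g (1.97 ± 0.59) were higher in colonocytes, and Clu (-0.26 ± 0.52), Ccl20 (-0.52 ± 0.56) and Timp1 (0.31 ± 0.42) did not pass. With no doublets removed, Clu turned to 3.05 in favour of colonocytes.

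Of 273 list genes tested, 175 were higher in colonocytes and 48 in undifferentiated cells (177 and 48 adjusted over the list alone), and over all 13975 genes 5359 and 4807. Hypoxia and glycolysis genes were higher in colonocytes for 22 of 23, antimicrobial genes for 16 of 21, inflammasome genes for 16 of 24 (2 lower), epithelial repair genes for 11 of 16 (1 lower), receptors for 17 of 25 (3 lower), cytokines for 12 of 16, chemokines for 16 of 24 (3 lower), dissociation stress genes for 15 of 22 (6 lower), growth factors for 8 of 14 (3 lower), MHC class II presentation genes for 6 of 8, eicosanoid genes for 6 of 13 (2 lower), matrix genes for 6 of 16 (3 lower) and niche factors for 1 of 6 (2 lower). Several passing genes belong to immune cells and lay at low levels, such as Ifng at 2.39 ± 0.694 against 1.12 ± 0.532 CPM and Il10 at 1.25 ± 0.806 against 0.392 ± 0.0314 CPM. Of the 1082 colonocytes of library 1, 322 and 123 lay in subclusters that held 9 and 6 cells of library 2. With no replicate block, 144 list genes were higher in colonocytes and 44 in undifferentiated cells, and Ifng and Il10 were no longer past the threshold. Members of near-identical gene groups (the Saa, Reg3, Ifit, Sprr, Ly6 and Gsdmc genes, Ccl21a and immunoglobulins) can share reads, so their separate levels are uncertain.

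**Figure D3:**
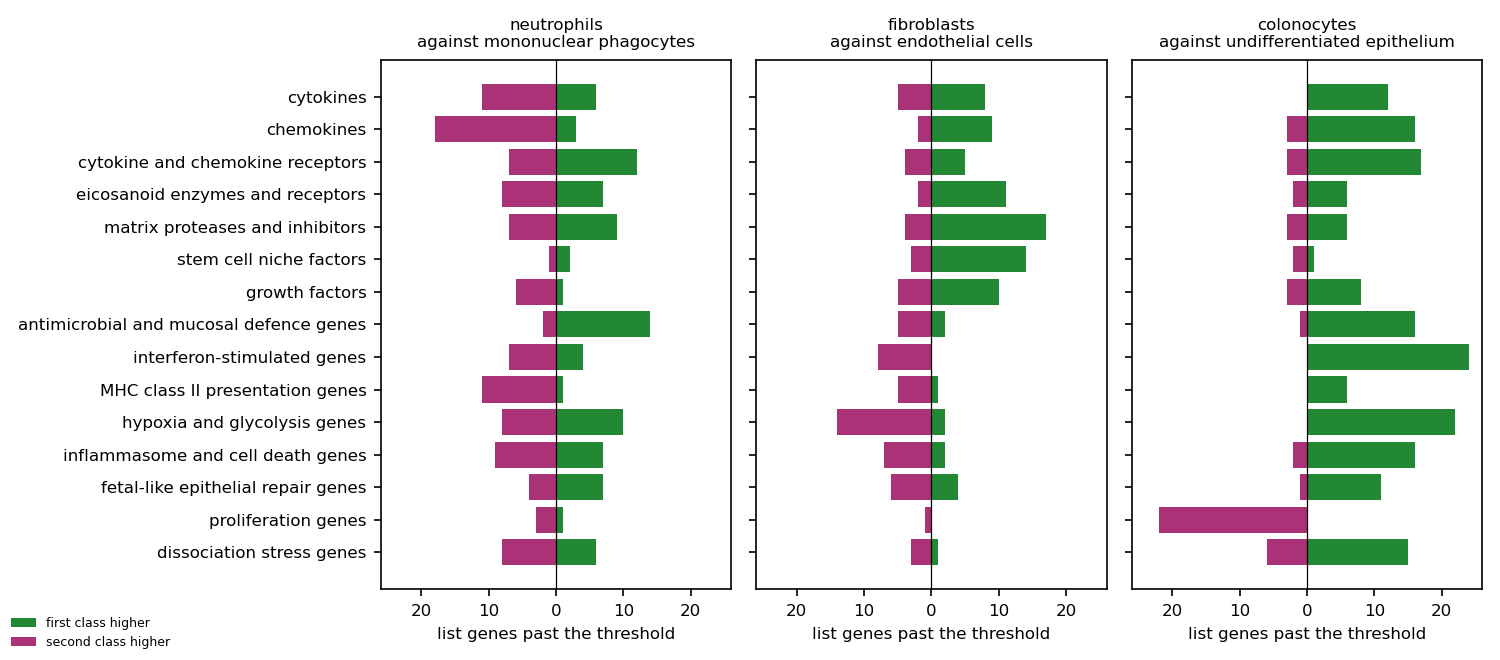
Number of list genes past an adjusted p of 0.05 in each list (y axis) for the 3 pairs of classes, as bars to the right where the first class was higher (green) and to the left where the second was (purple). In colonocytes 24 interferon-stimulated genes were higher, and in undifferentiated cells 22 proliferation genes.

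Between the libraries, 3638 genes had at least 50 CPM in either library, and 94.8% of them lay within 2-fold (SD of the log2 ratio 0.480, median 0.11). Higher by over 2-fold were 116 genes in library 2 and 72 in library 1. Genes with the largest ratios included epithelial genes lower in library 2, namely Gsdmc4 (121 and 9.49 plain CPM in libraries 1 and 2, log2 ratio -3.54), Tgm3 (-2.99), Ces2a (-2.94), Cyp2c55 (-2.80), Sycn (-2.64) and the enteroendocrine peptide Pyy (-2.82). Within epithelial cells, Gsdmc4 stood at 187 and 20.6 CPM and Cyp2c55 at 623 and 128 CPM, and the mix of epithelial cells differed too, with 746 and 172 cells in the cluster led by Aqp8 and Cyp2c55 and 131 and 49 in a subcluster with Gsdmc4 among its leading genes. The immunoglobulin genes Iglc1 (-2.36) and Ighg2c (-2.05) were also lower in library 2, while Ly6i (20.6 and 95.2 CPM, 2.16) and the interferon-induced chemokine Cxcl10 (106 and 460.5 CPM, 2.11) were higher, with Cxcl10 at 580.3 and 1431 CPM within phagocytes.

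Interferon-stimulated genes were higher in library 2 in several classes. Their median log2 ratio was 0.84 in phagocytes, where 21 of 21 expressed members lay above the median ratio of all genes of the class, 0.80 in endothelium (18 of 19), 0.80 in neutrophils (16 of 18), 0.63 in plasma cells (8 of 11) and 0.50 in lymphoid cells (19 of 19). In B cells, epithelium, fibroblasts and mast cells the medians were 0.04, 0.00, -0.14 and -0.21. The epithelial median cannot be told apart from a changed mix. The epithelial cluster with 746 and 172 cells had 24 of 24 interferon-stimulated genes higher than the other epithelial clusters. That with 320 and 407 cells had 23 higher and that with 354 and 238 cells 12. Those with 196 and 226 and with 144 and 135 cells had 23 of 24 lower. In neutrophils Ifit1 stood at 13.5 and 68.9 CPM, in endothelium Gbp2 at 517 and 1784 CPM and in phagocytes Irf7 at 53.8 and 119 CPM. Counted in the same way, 22 of 22 proliferation genes lay above the class median in epithelium (median ratio 0.84) and in lymphoid cells (0.37). The mix of cells differed here as well, with 70 and 170 cells in the dividing epithelial subcluster and 128 and 254 in the dividing lymphoid cluster. Matrix genes in phagocytes lay below the class median for 10 of 10 (median ratio -0.55), MHC class II presentation genes in epithelium for 7 of 7 (-0.73) and antimicrobial genes in epithelium for 15 of 18 (-0.50). The mix moved here too, but not in a single direction for these lists. The epithelial cluster with 746 and 172 cells had 7 of 12 MHC class II presentation genes and 12 of 23 antimicrobial genes higher than the other epithelial clusters. That with 320 and 407 cells had 3 and 11 of these higher, with 0 and 4 lower. The phagocyte cluster with 120 and 798 cells had 4 of 26 matrix genes lower than the other phagocyte clusters. That with 141 and 748 cells had 6 higher and 1 lower. The median in plasma cells lay at percentile 99.65 of matched random lists, and those in phagocytes, endothelium, neutrophils and lymphoid cells lay higher. Random lists do not match how far members of a list vary together, and some other lists were as extreme. In lymphoid cells MHC class II presentation and proliferation genes lay at percentile 100 and antimicrobial genes at 0. Chemokines in B cells lay at 100. The percentiles thus do not set interferon-stimulated genes apart. With 1 library on each side these values have no replicate check and describe these libraries. Transcripts typical of 1 class were also counted at low levels in the others. The neutrophil gene S100a8 (147482 plain CPM in neutrophils) stood at 317 to 646 CPM in other classes but 3421 in phagocytes, and the epithelial Krt8 (5661) at 139 to 371 CPM outside the epithelium. Some of these levels differed between the libraries. In plasma cells S100a8 stood at 182 and 741 CPM in libraries 1 and 2, Saa3 at 76.3 and 262 and Il1b at 39.4 and 213. Krt8 there stood at 121 and 164 CPM and Reg3b at 103 and 100. The rise of interferon-stimulated genes in plasma cells was not told apart from such RNA. In both libraries Y-linked genes were expressed (221 and 236 CPM), with 10 and 6 counts of Xist.

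**Figure D4:**
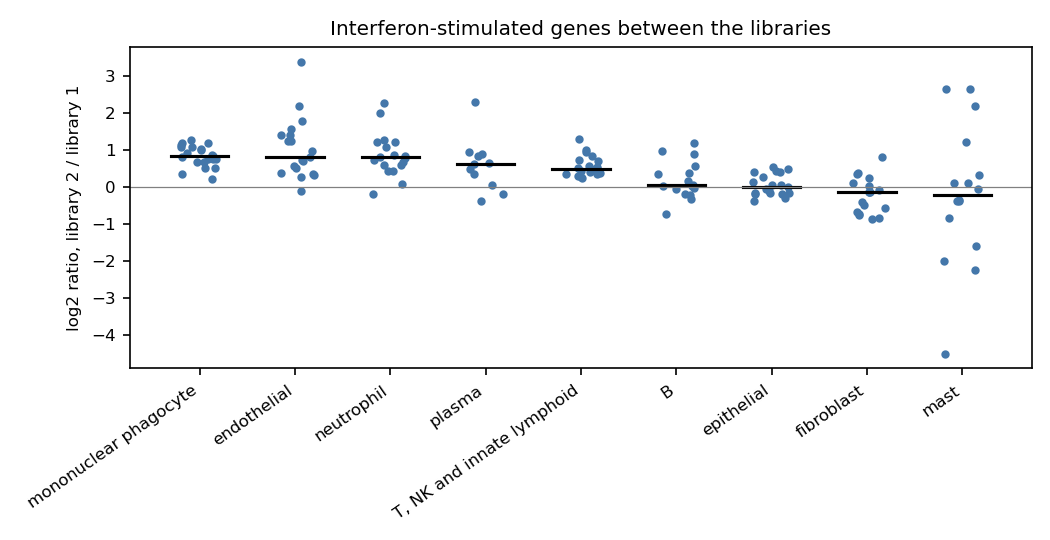
Log2 ratio of plain CPM, library 2 over library 1 (y axis), of each interferon-stimulated gene (points) in each class (x axis), with black bars at the class medians. The medians were 0.84 in phagocytes, 0.80 in neutrophils and 0.00 in epithelium.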

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

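The tests of neutrophil RNA, of the mitochondrial filter and of doublet removal were chosen only after the results they measure were seen. For the test of free RNA the comparison with B cells, and for the test of other Ly6 genes a second version and the use of the spread between libraries, were also added after a first value had been seen. The labels give 1 group, so no biological explanation was tested.

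Some cells stayed outside every comparison although they held signal above the limit a count of 0 allows. A cluster of 323 barcodes (120 in library 1 and 203 in library 2, median 1148 UMIs) held S100a8 at 5540.4 CPM, the myeloid receptor gene Csf1r at 371 CPM and Krt8 at 751 CPM. Another of 304 barcodes (164 and 140, median 1185 UMIs) held the smooth muscle genes Tagln at 5363 CPM and Myh11 at 3387 CPM, with Krt8 at 1806 CPM, and 19.1% of its cells held 2 markers of the class it came closest to.

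Interferon-stimulated genes were higher in library 2 in phagocytes, neutrophils, endothelium and lymphoid cells. Free RNA as the whole cause was argued against in lymphoid cells and neutrophils. With free RNA subtracted, the list's median excess over the class median went from 0.44 to 0.42 in lymphoid cells. In neutrophils it went from 0.69 to 0.76. The lower bound was 0.32 over resampled list genes, which measures spread between genes and not between libraries. In B cells the excess was 0.01 (bootstrap interval over genes -0.14 to 0.34). Free RNA was not subtracted in phagocytes, endothelium or plasma cells. A different mix of phagocyte clusters stays open for phagocytes, since the excess averaged 0.55 over 5 clusters with an SD of 0.49, with 0.33, 0.52, 0.66 and 1.27 in 4 of them and -0.06 in the cluster with 120 and 798 cells. The lymphoid mix moved too and was not tested as a cause: the CD4 T cluster held 351 and 969 cells, and 12 of 24 interferon-stimulated genes were higher in it than in the other lymphoid clusters.

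Ly6g, a neutrophil surface gene by its usual use, stood at 497 ± 51.2 plain CPM in epithelial cells and 369 ± 50.8 in neutrophils. Neutrophil RNA in epithelial droplets was argued against, since Ly6g per S100a8 UMI was 742.7 and 534.8 times as high in epithelial cells as in neutrophils. Reads shared with Ly6m stay open, because the overall factor came from a subcluster with 322 cells of library 1 and 9 of library 2, and library 2 by itself passed the bound by less than the SD. A constant leak from Ly6m overstated Ly6g by up to 11.6-fold, with 12.03 and 5.65 in the libraries (SD 4.51) against a bound of 5, and an earlier version of the test gave 5.74. For the other 14 Ly6 genes the factor was at least 13.5.

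The epithelial share was 2.35 times as high in library 1 as in library 2. With barcodes up to 40% mitochondrial UMIs kept the ratio was 2.26, and with no doublets removed it was 2.46, which argues against either filter as the whole cause. This outcome largely followed from the numbers removed, which were too small to even out the shares. In libraries 1 and 2, 876 and 484 barcodes lay above the mitochondrial limit, and 302 and 702 were removed as doublets. Differences in tissue sampling or dissociation were not tested.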

How the results depend on the processing

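The alternatives without the unnamed epithelial subclusters and with the Ly6g-led subcluster counted as colonocytes were chosen after seeing the data, and no count moved by over 1.5 times under them. Of 2008 values of 217 gene results under alternatives with a test, 1905 kept their side of the threshold, 69 lost a call, 12 gained one and 22 turned. Among the 1905, called results also kept their direction, and the direction of results without a call was not compared. Leaving out a library leaves no test. There direction was compared only for results called in the main fit. Of 434 values, including those not compared, 1 turned. List genes with a source class numbered 166 to 247 over the alternatives, against 219. With a minimum of 500 genes per cell, the fibroblast lead turned to -5.98 for Il11, -1.92 for Cxcl5, -1.94 for Cxcl13, -2.95 for Mmp3, -10.35 for Mmp10, -2.81 for Wnt5a and -0.045 for Grem1, and the endothelial lead for Cxcl1 to -0.66, all behind the smooth muscle and pericyte class. That class also led with no doublets removed and at Scrublet's automatic threshold, for Cxcl1 (-1.20 and -1.23), Ccl2 (-0.27 and -0.26), Mmp3 (-0.34 and -0.45) and Mmp10 (-0.39 and -0.50). With no doublets removed, Ifng turned to 2.40 in neutrophils against phagocytes, Reg3b and Reg3g to 1.05 and 0.93 in fibroblasts against endothelium, and Clu to 3.05 in colonocytes against undifferentiated cells. At Leiden resolution 0.5 epithelium led for Il11 (-0.95) and Mmp10 (-5.21). The fibroblast class held 39 and 97 cells there and 36 and 91 with 500 genes, against 77 and 166, so cells had moved to other class names. Leaving out each library in turn gave an endothelial lead for Ccl2 of -0.10 to 1.38. The share of lymphoid cells was 32.7% and 29.5% with limits of 10% and 40% mitochondrial UMIs, 29.4% with no doublets removed and 29.3% at the automatic threshold. Plasma cells were 1.33% and 1.18% with the limits of 10% and 40%. Fibroblasts were 0.898% with 500 genes, 2.72% with no doublets removed, 2.76% at the automatic threshold, and 0.936% and 2.33% at resolutions 0.5 and 2.0. Smooth muscle cells and pericytes were 1.47% with 500 genes, 0.368% with the limit of 40%, 0.418% with no doublets removed, 0.425% at the automatic threshold, 0.388% at resolution 2.0 and 0.529% with libraries clustered apart. Endothelial source genes were 11 with DESeq2, 500 genes, the limit of 40%, no doublets removed and resolution 2.0. Fibroblast source genes were 22 with 500 genes and 33 under both doublet alternatives. DESeq2 gave 3 mast cell and 17 phagocyte source genes, and 135, 80 and 185 list genes lower in epithelium, phagocytes and lymphoid cells. With no doublets removed, phagocyte source genes were 20, and 41 and 34 list genes were lower in endothelium and mast cells. The fit with no replicate block lost 16 gene calls. Beyond these moves of cells between class names, the cause was not tested for any of these.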

Other observations

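All contrasts between clusters of a class were chosen after the data were seen. The list genes used were held out of the clustering, though genes that vary with them were not. The contrasts come from an edgeR fit of 28 clusters, 15252 genes and 346 list genes.

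The fibroblasts fell into a cluster closest to subepithelial Pdgfra-high cells (38 and 69 cells) and one closest to adventitial Cd34-high cells (39 and 97 cells). In the first, 88 list genes were higher, and in the second 29 (97 and 35 adjusted over the list alone). The subepithelial cluster held Mmp13 at 5955 ± 301 against 1.92 ± 0.0837 CPM in the adventitial cluster (adjusted p = 3.85e-21), with Nrg1 (3126 ± 183 CPM), Il1rl1 (2166 ± 462 CPM), Ereg (2547 ± 391 CPM), Il11 (1469 ± 1091 CPM), Ptgs2 (2260.3 ± 88.2 CPM) and Mmp3 (4057 ± 307 CPM). The adventitial cluster held Il33 at 953 ± 86.8 against 2.37 ± 0.0418 CPM, Cxcl12 at 1207 ± 309 against 86.3 ± 10.2 CPM, and Sfrp1 (1585 ± 484 CPM), Ccl11 (721 ± 33.5 CPM), Rspo3 (73.0 ± 34.0 CPM) and Timp1 (1148 ± 785 CPM). Matrix genes were higher in the subepithelial cluster for 13 of 26 and in the adventitial cluster for 2.

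Endothelial cells fell into a cluster closest to blood vessels (36 and 85 cells) and a lymphatic one (30 and 51 cells). Cxcl9 stood at 1693 ± 896 CPM in the first and 22.6 ± 31.9 CPM in the second, Cxcl1 at 958 ± 331 and 37.0 ± 4.42 CPM and Ccl2 at 579 ± 448 and 19.9 ± 0.214 CPM. Ccl21a stood at 2.85 ± 0.913 CPM in the blood vessel cluster and 5989 ± 435 CPM in the lymphatic one.

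Among phagocytes, the monocyte-like cluster with 141 and 748 cells held Nos2 at 2122 ± 113 CPM, Il1a at 1225 ± 441 CPM, Ptges at 177 ± 38.4 CPM and Tnf at 623 ± 109 CPM, and 18 of 24 interferon-stimulated genes and 20 of 23 hypoxia and glycolysis genes were higher in it than in the other phagocyte clusters. The monocyte-like cluster with 230 and 474 cells held Cxcl2 at 24466 ± 7219 CPM, Il1b at 15557 ± 1016 CPM, Cxcl3 at 3075 ± 1037 CPM and Osm at 636 ± 26.2 CPM, with 10 of 24 interferon-stimulated genes lower. Dendritic-like cells held Ccl22 at 131.5 ± 9.86 CPM and Il12b at 124 ± 47.7 CPM, and a macrophage-like cluster Ccl8 at 541 ± 13.0 CPM and Pf4 at 316 ± 168 CPM.

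Among lymphoid cells, a cluster closest to gamma delta T cells (99 and 100 cells) held Il22 at 2952 and 565 CPM and Il17a at 1182 and 167 CPM in libraries 1 and 2. Its leading genes included Calca, from the marker list of type 2 innate lymphoid cells, as well as Trdc. Of its cells, 78.9% held 2 of the markers. Innate lymphoid cells within it were not told apart from gamma delta T cells. A cluster closest to regulatory T cells (87 and 20 cells) held Il10 at 440.1 ± 327 CPM, Areg at 268 ± 34.1 CPM and Ebi3 at 48.9 ± 10.2 CPM, and a CD4 T cluster (351 and 969 cells) held Ifng at 634 ± 95.5 CPM. In epithelium, a colonocyte-like cluster with 320 and 407 cells held Areg at 786 ± 20.9 CPM and Ly6a at 6584 ± 459 CPM, and that with 746 and 172 cells Nos2 at 911 ± 347 CPM and Saa1 at 13625 ± 1433 CPM.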
